A study of Mus musculus with 8 samples.

How the data were processed

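Poly(A)-selected RNA from mouse liver was sequenced in 8 libraries, 4 of a control group and 4 of a resmetirom group, taken from the titles of the samples. Per the labels' protocols, mRNA was captured with oligo(dT) beads, fragmented, copied into cDNA and sequenced on an MGI DNBSEQ-T7 or an Illumina NovaSeq X Plus, and which library went on which instrument is not given in the sources used here. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.1.0, StringTie 1.3.1, RSEM, DESeq2, edgeR and the genome build mm10, with no role or order, so which of them made each column is not given in the sources used here. Strand handling and the treatment of reads shared between gene copies are not given either, so reads of overlapping or antisense genes could not be told apart. Such handling can move counts between members of a gene family without changing their sum.

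The authors deposited 1 table of 22013 genes with whole-number counts per gene and library, per the file headers and the values, of which 5994 genes had no counts. The authors also deposited TPM values, which correct for gene length and fix the sum of every library. Per the file headers, the authors' table further holds a log2 fold change, which the values show to be the log2 ratio of the group means of TPM with a mean of 0 replaced by 0.001. The authors' table gives a p-value and an adjusted p-value for each gene, per the file headers, and the tool behind them is not given in the sources used here. Values that sum to a fixed total shift all other genes when a few abundant genes change, which applies to TPM and to counts scaled by library size alone. Every per-sample column was matched to a sample by its name, and 0 columns were left unmatched.

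Counts per library summed to 16787561 to 19887539. Genes were tested with edgeR 4.0.16 in R 4.3.3, after filterByExpr had kept 12207 genes, with TMM factors, robust dispersion and robust quasi-likelihood fits (glmQLFit, glmQLFTest), and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 fold changes are resmetirom minus control, and each SE is the size of the change divided by the square root of the F statistic. Levels are CPM scaled by the TMM factors. Where a group had no counts the fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio of summed counts is given with an exact 95% binomial interval, and both cover counting error only. The TMM factors were 1.06 to 1.16 in the control libraries and resmetirom replicate 1, and 0.804 to 0.879 in resmetirom replicates 2 to 4. Single library measures were compared with 2-sided exact permutation tests, whose smallest p with 4 against 4 libraries is 0.0286.

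Before the data were examined, 41 gene lists were fixed (metabolic pathways, nuclear receptor targets, liver zones, sex-biased genes, and markers of other cell types and tissues), as was the rule for the genes to name. The rule took the 8 largest rises and 8 largest falls among called genes with an assigned symbol, a mean of at least 1 CPM and fully separated groups, a fixed panel of 20 genes, and up to 4 called members of each list with the smallest p, or else the member with the smallest p. Some genes that this rule takes are not reported here. Lists with at least 5 tested members (36 of 41) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. Beside it, camera with an estimated correlation and fry were run. With an estimated correlation, 1 list (female-biased genes) was called higher and 0 lower, against 7 and 4 with the preset one, and all of the other 34 splits of the libraries had at least 1 list called with the preset one. Enrichment of the table's own pathway annotation used terms of 10 to 300 tested genes. Chromosome positions and exonic lengths came from GENCODE release M21 on GRCm38, the assembly that mm10 names, where 99.4% of the table's gene identifiers were found.

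Libraries of 1 group were compared before they were averaged: the chi-square per degree of freedom of every pair was 13.8 or more, so none was the same library sequenced again. This value measures differences beyond counting error and cannot show whether libraries came from the same RNA or animal. The procedure was tested on simulated counts of this comparison, with 12124 genes in its test step and 50 genes changed at each fold. It recovered 34% of genes changed 1.5-fold, 78% at 2-fold, 94% at 4-fold and 100% at 8-fold, with 8 false calls among 161. The changed genes were drawn from those with a mean of at least 1 CPM, so the rates do not cover rarer genes. Both groups had the same means before the changes, so neither the shift of the Mup share nor a deviating library was simulated. In that simulation the 1 list that was moved was called, as was 1 of 34 lists that were not. The simulated genes were drawn independently, so this rate does not carry over to lists whose genes are correlated.

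Alternatives fixed before the data were examined were other scalings (RLE, upper quartile, library size only), leaving out the 20 most abundant genes, DESeq2 1.42.0, limma-voom, fits without robust estimation, no low-count filter or a filter of at least 1 CPM in 4 samples, stricter thresholds, genes with an assigned symbol only, a block for the replicate number, leaving out each library, and the authors' deposited comparison. Alternatives on TPM (limma-trend on log2(TPM + 1) or log2(TPM + 0.1)) and without the Mup genes were added after the data were seen. Xist was not analysed here.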

Results

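Liver transcriptomes of mice were profiled by sequencing of poly(A)-selected RNA in 8 libraries, 4 labelled control and 4 labelled resmetirom. Resmetirom is an agonist selective for the beta form of the thyroid hormone receptor, which is the main form in hepatocytes. The series describes a model of metabolic dysfunction-associated steatohepatitis, a fatty liver disease with inflammation, in which mice ate a diet rich in fructose, palmitate and cholesterol for 12 weeks. Resmetirom was injected intraperitoneally at 5 mg/kg/day, starting after 4 weeks of the diet and lasting 8 weeks. The vehicle held 0.5% carboxymethyl cellulose sodium and 0.4% Tween-80. The labels of the control libraries state neither their diet nor whether they received vehicle. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries. The gene counts summed to 16787561 to 19887539 per library, and 13902 to 14442 genes had at least 1 count. Log2 CPM correlated at r = 0.963 to 0.986 between libraries of 1 group and at r = 0.938 to 0.964 between libraries of different groups, over genes, which are not independent replicates. The first principal component held 41.5% of the variance and separated the groups, with all 4 control libraries at or below -27.3 and all 4 resmetirom libraries at or above 24.2.

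The design has 1 comparison, resmetirom against control. Diet and vehicle are not given for the control libraries, so a difference in either cannot be told apart from an effect of the drug. In the resmetirom libraries, 24 of 25 genes of cholesterol synthesis and uptake rose, with a median log2 fold change of 2.43, while the sterol exporter genes Abcg5 and Abcg8 and the desaturase gene Scd1 fell, by 1.64, 1.5 and 1.88 on the log2 scale. Of 18 genes that mouse livers express more in females 10 rose, some of them from no more than 3 counts over all control libraries, and of 21 male-biased genes 9 fell and 2 rose. Of 12207 genes tested with edgeR's quasi-likelihood test, 317 were higher and 243 were lower with resmetirom at a Benjamini-Hochberg adjusted p under 0.05. Of these, 127 and 111 changed at least 2-fold. All 4 libraries of 1 group lay above all 4 of the other for 550 of the 560 called genes. Such separation was seen in 11.8% of all tested genes, against 2.86% by chance. Without control replicate 4 the counts were 182 higher and 149 lower, and without resmetirom replicate 4 they were 208 and 161. With library sizes as the only scaling, the median log2 fold change of all tested genes moved from -0.0043 to -0.31 and the calls split into 151 higher and 1961 lower. That way 92.9% of calls were lower against 43.4% with TMM factors. Changes are given relative to the TMM scaling. With library sizes only, the medians of the lists of fatty acid synthesis, bile acids, sterol efflux, glucose metabolism, peroxisomal oxidation, monocytes, cholangiocytes, stress response and hepatocyte identity, which camera did not call, turned from above to below 0. Camera with its preset correlation called 7 of 36 gene lists higher and 4 lower, but 1 and 0 with an estimated correlation. In the other 34 splits of the 8 libraries it called a median of 10 lists. Some of these splits keep most libraries of a group together and so hold part of the group difference. Counts of splits are therefore not rates of calls by chance.

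Of the 25 tested genes of cholesterol synthesis and uptake, all targets of the transcription factor SREBP2, 24 rose and none fell, and all 25 passed when adjusted over the list alone. Their median log2 fold change was 2.43, and in every one of the 25 the 4 resmetirom libraries lay above the 4 control libraries. Srebf2, which encodes SREBP2 itself (ENSMUSG00000022463, chromosome 15, 82147181 to 82205379), was at 14.6 ± 2.12 CPM in the control libraries and 43.5 ± 8.65 CPM in the resmetirom libraries (SD, n = 4 each), a log2 fold change of 1.57 (SE 0.15, adjusted p = 0.000109). Tm7sf2, which encodes a sterol reductase, rose by 2.38 (SE 0.25, adjusted p = 0.000843). Sqle and Idi1, named after their values were seen, had the 2 highest fitted changes of the list, 7.77 (SE 0.70) and 6.09 (SE 0.65). Fdft1 was the member not called, at 1.97 (SE 0.43, adjusted p = 0.0529), and passed without resmetirom replicate 3 (adjusted p = 0.00127), with DESeq2 (adjusted p = 0.000272), with limma-voom (adjusted p = 0.0180), without robust estimation (adjusted p = 0.00932), on the log2(TPM + 1) scale (adjusted p = 0.0260) and on the log2(TPM + 0.1) scale (adjusted p = 0.0257). The list was called by camera with a preset correlation (adjusted p = 2.75e-34), with adjusted p = 0.202 with an estimated correlation. The test fry, which compares a list with no other genes, called it higher (adjusted p = 0.00239).

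Among 24 tested genes of sterol efflux and lipoproteins, 3 rose and 7 fell, and 4 and 9 did when adjusted over the list alone. Abcg5 and Abcg8 encode the subunits of the transporter that secretes cholesterol into bile. Abcg5 (ENSMUSG00000040505, chromosome 17, 84658234 to 84683011) fell from 225 ± 15.4 to 72.1 ± 1.27 CPM (SD, n = 4 each), a log2 fold change of -1.64 (SE 0.08, adjusted p = 3.39e-07), and Abcg8 had -1.5 (SE 0.18, adjusted p = 0.000862). Of the lipoprotein genes, Apoa4 rose by 0.77 (SE 0.11, adjusted p = 0.00166) and Apoc3 by 0.63 (SE 0.10, adjusted p = 0.00353), the second of which was not called with library sizes only (adjusted p = 0.0878). The median of the list was 0.05 while its mean was -0.18 and its camera direction was down, and camera did not call the list (adjusted p = 0.276). The test fry, which asks whether the genes of a list move on balance in 1 direction and compares them with no other genes, called it lower (adjusted p = 0.00864). The efflux list had 1 higher and 11 lower with library sizes only, and 0 and 14 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Its median was -0.26 with library sizes only, -0.53 on the log2(TPM + 1) scale, -0.55 on the log2(TPM + 0.1) scale, 0.075 without control replicate 2, 0.020 without control replicate 3, -0.003 without resmetirom replicate 1, -0.0001 without resmetirom replicate 2 and 0.010 without resmetirom replicate 3.

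**Figure D1:**
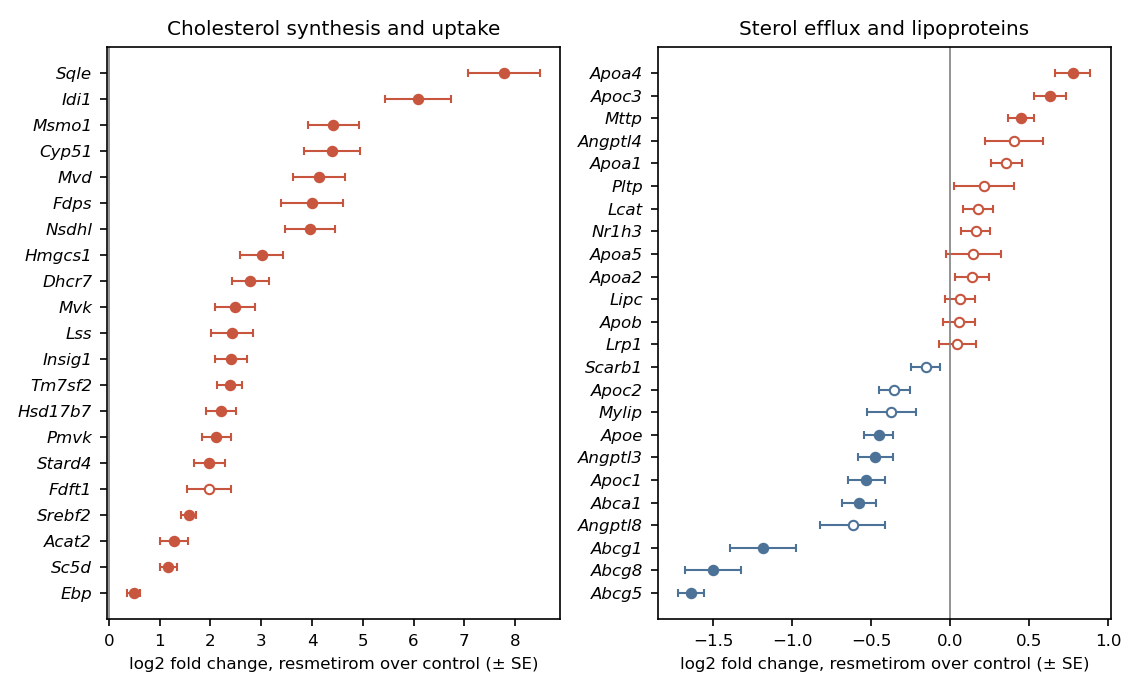
Fitted log2 fold changes, resmetirom over control, of tested members of the lists of cholesterol synthesis and uptake (left, 21 of 25 members drawn) and of sterol efflux and lipoproteins (right, 24 of 24 drawn), 4 libraries per group. Points are edgeR estimates and bars are 1 SE, filled where the adjusted p is under 0.05, red above 0 and blue below; of the members drawn, 20 are called higher on the left, and 3 higher and 7 lower on the right.

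Genes of fatty acid and triglyceride synthesis changed in both directions, with 5 higher and 3 lower of 23 tested (8 and 3 when adjusted over the list alone). The desaturases of polyunsaturated fatty acids rose, Fads1 by 1.45 (SE 0.11, adjusted p = 1.16e-05) and Fads2 by 0.88 (SE 0.10, adjusted p = 0.000493). Scd1, the desaturase that makes oleate (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), fell from 10303 ± 1895 to 2808 ± 898 CPM (SD, n = 4 each), a change of -1.88 (SE 0.21, adjusted p = 0.000793). Mlxipl, which encodes the carbohydrate-responsive factor ChREBP, fell by 0.75 on the log2 scale (SE 0.12, adjusted p = 0.00283). Srebf1, at -1.53 (SE 0.34, adjusted p = 0.0478), was called with all libraries but not without control replicate 2, 3 or 4 or resmetirom replicate 1, 3 or 4, where its adjusted p was 0.0857 to 0.127, nor with upper-quartile factors (adjusted p = 0.0539) or without a low-count filter (adjusted p = 0.0831). Fasn, the fatty acid synthase, was at 1.14 (SE 0.27, adjusted p = 0.0513), and passed without control replicate 1 (adjusted p = 0.0265) or resmetirom replicate 3 (adjusted p = 0.00230), and with DESeq2 (adjusted p = 6.57e-05), with limma-voom (adjusted p = 0.0254), without robust estimation (adjusted p = 0.0219) and with the filter of at least 1 CPM in 4 samples (adjusted p = 0.0498). The list as a whole was not called by camera (adjusted p = 0.0904). It was called higher with library sizes only (adjusted p = 0.00988), without control replicate 2 (adjusted p = 0.0325) and without resmetirom replicate 3 (adjusted p = 0.0148). Camera compares a list with the other genes. With library sizes only, the median of all tested genes was -0.31 and that of the list was also below 0, so that call does not show a rise. Fatty acid and triglyceride synthesis genes had 3 higher and 6 lower with library sizes only, and 2 and 8 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 3 higher and 3 lower without control replicate 3, 3 and 2 without control replicate 4, and 8 and 2 without resmetirom replicate 3. Of 21 tested genes of lipid droplets and fatty acid uptake, 1 rose and 5 fell (2 and 7 when adjusted over the list alone), among them Vldlr at -1.99 (SE 0.23, adjusted p = 0.000478), the droplet coat gene Plin4 at -1.66 (SE 0.25, adjusted p = 0.00317), Fabp4 at -0.996 (SE 0.17) and Hsd17b11 at -0.69 (SE 0.12), with a camera adjusted p of 0.297. The droplet and uptake list had 0 higher and 8 lower with library sizes only, 2 and 6 with DESeq2, and 0 and 11 on the log2(TPM + 1) and log2(TPM + 0.1) scales. It had 0 higher and 5 lower without control replicate 2 or resmetirom replicate 4, and 0 and 4 without control replicate 4 or resmetirom replicate 3. Markers of adipocytes, a neighbouring tissue, of which Fabp4 is 1, had a median of -0.78 over 4 tested, with 1 lower, or 3 lower when adjusted over the list alone. The adipocyte median was -1.19 on the log2(TPM + 1) scale, -1.28 on the log2(TPM + 0.1) scale and -0.49 without resmetirom replicate 4.

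Of 17 thyroid hormone responsive liver genes, 4 rose and none fell, and 6 and 0 did when adjusted over the list alone, with a median log2 fold change of 0.52. The median was 0.19 with library sizes only and -0.013 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Thyroid hormone responsive genes had 2 higher and 1 lower with library sizes only or on the log2(TPM + 1) and log2(TPM + 0.1) scales. Called members included the malic enzyme gene Me1 at 0.68 (SE 0.11, adjusted p = 0.00405), the carnitine transferase gene Cpt1a at 0.58 (SE 0.11, adjusted p = 0.00916), and the amino acid and iodothyronine transporter gene Slc16a10 at 0.64 (SE 0.12, adjusted p = 0.00813). With library sizes only, Me1 (adjusted p = 0.0657), Cpt1a (adjusted p = 0.155) and Slc16a10 (adjusted p = 0.0878) were no longer called. Dio1, the deiodinase gene used as a readout of hepatic thyroid hormone action, was at 46.2 ± 18.2 CPM in the control libraries and 114 ± 29.0 CPM in the resmetirom libraries (SD, n = 4 each) and at 1.31 (SE 0.30, adjusted p = 0.0550). It passed without control replicate 1 (adjusted p = 0.00761) or resmetirom replicate 2 (adjusted p = 0.0210), and with DESeq2 (adjusted p = 1.90e-05), with limma-voom (adjusted p = 0.0142), with upper-quartile factors (adjusted p = 0.0482), with library sizes only (adjusted p = 0.0476) and without robust estimation (adjusted p = 0.0184). Thrsp was not called at -0.25 (SE 0.42, adjusted p = 0.835), and was at 0.14 without control replicate 2. Also not called were Klf9 at 0.52 (SE 0.22, adjusted p = 0.248), Thrb at -0.28 (SE 0.15, adjusted p = 0.380), Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.31 (SE 0.63, adjusted p = 0.357), and Fgf21 at 1.18 (SE 0.46, adjusted p = 0.227). Thrb passed with library sizes only (adjusted p = 0.0241). Hr was at 1.15 (SE 0.51, adjusted p = 0.267) and passed without control replicate 1 (adjusted p = 0.0411). Camera called the list higher (adjusted p = 7.35e-05), with adjusted p = 0.0592 with an estimated correlation. Fry also called it higher (adjusted p = 0.00239).

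Camera called the lists of mitochondrially encoded transcripts and of nuclear-encoded oxidative phosphorylation higher, each at an adjusted p of 1.46e-10. Neither held when the correlation between genes was estimated, with adjusted p = 0.287 for the mitochondrial and 0.567 for the nuclear list with an estimated correlation. The test fry, which compares a list with no other genes, called both higher (adjusted p = 0.00864 for the mitochondrial and 0.0337 for the nuclear list). Of the 13 tested transcripts encoded by the mitochondrial genome, 9 rose and none fell (13 and 0 when adjusted over the list alone), with a median of 0.53. That median was 0.21 with library sizes only and 0.021 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Mitochondrially encoded transcripts had 2 higher and 0 lower with library sizes only, 5 and 0 of the 5 tested without the 20 most abundant genes, and 0 and 0 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 3 higher and 0 lower without control replicate 4, and 4 and 0 without resmetirom replicate 4. mt-Nd6 rose by 0.75 (SE 0.10, adjusted p = 0.00102), mt-Cytb by 0.59 (SE 0.12), mt-Co2 by 0.52 (SE 0.11) and mt-Co3 by 0.52 (SE 0.11). None of these except mt-Nd6 was called with library sizes only. The gene mt-Nd6 lies on the opposite strand to mt-Cytb, mt-Co2 and mt-Co3. Since strand handling is not given, antisense reads among its counts could not be told apart. The call of mt-Co3 was also lost without control replicate 4 (adjusted p = 0.0614). The share of all counts in mitochondrial transcripts was 8.82% ± 0.986 in the control and 9.47% ± 0.699 in the resmetirom libraries (SD, n = 4 each; exact permutation test, 2-sided p = 0.343). Of 47 nuclear-encoded subunits, 7 rose and none fell (20 and 0 when adjusted over the list alone). Their median of 0.22 turned below 0 with other scalings. It was -0.089 with library sizes only and -0.28 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Nuclear-encoded subunits had 0 higher and 3 lower with library sizes only, 15 and 0 with DESeq2, 4 and 0 without robust estimation, and 0 and 12 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 2 higher and 0 lower without control replicate 2, 4 and 0 without control replicate 3 or resmetirom replicate 1, 1 and 0 without control replicate 4 or resmetirom replicate 4, and 3 and 0 without resmetirom replicate 3. Cox7b was at 0.54 (SE 0.09, adjusted p = 0.00501), a call not reached with library sizes only (adjusted p = 0.196). In the other 34 splits of the 8 libraries, 1 split gave as small a p for each list. Across genes, log2 fold change fell slightly with exonic length (Spearman rho = -0.111 over genes, which are not independent), and both lists hold short transcripts, with a median exonic length of 784 and 1928 bases. After the length trend was taken out, the medians were 0.26 and 0.13 and the camera adjusted p values 0.000110 and 4.09e-05. Mitochondrial fatty acid oxidation and ketogenesis had 2 higher (Cpt1a and Bdh1) and 1 lower (Acsl1) of 23 genes, and 8 and 1 when adjusted over the list alone. Mitochondrial fatty acid oxidation had 0 higher and 2 lower with library sizes only, 5 and 1 with DESeq2, and 0 and 7 on the log2(TPM + 1) and log2(TPM + 0.1) scales. With library sizes only, the calls of Cpt1a (adjusted p = 0.155) and Bdh1 (adjusted p = 0.271) were lost. The median of this oxidation list, 0.16, turned as well. It was -0.14 with library sizes only and -0.34 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Its camera adjusted p of 0.000407 became 0.331 with library sizes only, and 4 of the 35 splits gave as small a p. It was adjusted p = 0.668 with an estimated correlation. Peroxisomal and microsomal oxidation had 3 higher and none lower of 20 (7 and 0 when adjusted over the list alone), led by Cyp4a31 at 1.62 (SE 0.16, adjusted p = 0.000191), and was not called as a list (adjusted p = 0.0553). Camera called it higher with voom weights (adjusted p = 0.0369), without control replicate 2 (adjusted p = 0.0115) and without resmetirom replicate 1 (adjusted p = 0.0320). Peroxisomal and microsomal genes had 1 higher and 5 lower with library sizes only, 6 and 0 with DESeq2, and 1 and 8 on the log2(TPM + 1) and log2(TPM + 0.1) scales.

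Of 18 tested female-biased genes, 10 rose and none fell (13 and 0 when adjusted over the list alone), with a median of 2.63, which was unchanged with genes at 0 counts in the control group set to their lower bound. The female-biased median was 1.06 on the log2(TPM + 1) scale. Sult2a1, a hydroxysteroid sulfotransferase (ENSMUSG00000078798, chromosome 7, 13796246 to 13837409), had 3 counts over the 4 control libraries and 55349 over the 4 resmetirom libraries, a ratio of 24744 after scaling (95% interval 8466 to 119990, exact binomial, counting error only). Without control replicate 3, which held all 3 counts, it was at least 18290-fold higher. Its relatives Sult2a2, Sult2a3 and Sult2a5 are not on the list. Sult2a5 had no counts in the control group and was at least 2514-fold higher, against a floor of 3 counts over the group. On the same floor Sult2a3 was at least 1065-fold higher and the cytochrome P450 gene Cyp3a44 at least 999-fold higher. Sult2a2 rose by 12.34 (SE 0.61, adjusted p = 5.00e-05), from 6 counts over the control libraries to 25507 over the resmetirom libraries, so the size of this fitted change depends on the prior count. Female-biased genes had 16 higher and 0 lower of the 24 tested with DESeq2, and 11 and 2 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Cyp2a4 rose from 95.6 ± 32.9 to 955 ± 74.7 CPM (SD, n = 4 each), while the prolactin receptor gene Prlr rose by 1.20 (SE 0.15, adjusted p = 0.000793). The call of Sult2a3 (adjusted p = 0.0448) was lost without any one control replicate and without resmetirom replicate 1, 3 or 4 (adjusted p = 0.0583 to 0.142), and without a low-count filter (adjusted p = 0.0855). Cyp3a41a, with 2 counts in the control group and a ratio of 3087 (95% interval 854 to 25495), was at 69.2 ± 74.6 CPM in the resmetirom libraries (SD, n = 4). Its ratio was 1474 without resmetirom replicate 1, and it was at least 1521-fold higher without control replicate 3, which held both counts. It was called (adjusted p = 0.0301) but not without any one control replicate or without resmetirom replicate 4 (adjusted p = 0.0800 to 0.265), nor with limma-voom (adjusted p = 0.216). Female-biased genes were the list that camera also called with an estimated correlation (adjusted p = 2.14e-15 with the preset one, adjusted p = 0.0186 with an estimated correlation).

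Male-biased genes were lower in 9 and higher in 2 of 21 tested members (12 and 4 when adjusted over the list alone), with a median of -1.61. Cyp4a12a, a fatty acid hydroxylase of male liver (ENSMUSG00000066071, chromosome 4, 115299046 to 115332815), fell from 302 ± 80.5 to 2.90 ± 1.6 CPM (SD, n = 4 each), a change of -6.72 (SE 0.47, adjusted p = 0.000343). Cyp4a12b was at -6.45 (SE 0.49), and Cyp2d9 at -2.86 (SE 0.14, adjusted p = 3.06e-07). The urinary protein genes Mup20 and Mup21 were at -3.96 (SE 0.25, adjusted p = 2.68e-05) and -6.43 (SE 0.41, adjusted p = 4.70e-05). The 2 members called higher, named after their values were seen, were Mup1 at 3.60 (SE 0.56) and Ces4a at 2.36 (SE 0.41). The call of Mup1 was lost without control replicate 2 (adjusted p = 0.0603) or control replicate 4 (adjusted p = 0.0681), and with a replicate block (adjusted p = 0.163). Male-biased genes had 4 higher and 11 lower of the 24 tested with DESeq2, 4 and 11 with limma-voom, 3 and 14 on the log2(TPM + 1) and log2(TPM + 0.1) scales, and 1 and 7 of the 15 tested without the Mup genes. They had 1 higher and 8 lower without control replicate 2 or 4. Camera called the list lower (adjusted p = 5.81e-06), with adjusted p = 0.471 with an estimated correlation. Fry also called it lower (adjusted p = 0.00545). The Sult2a, Cyp3a, Cyp4a12, Cyp2a, Gsta and Mup genes have near-identical copies, and how reads shared between copies were counted is not given in the sources used here, so the split of counts within each family is uncertain. All Mup genes together took 5.62% ± 1.13 of the counts in the control and 17.6% ± 7.39 in the resmetirom libraries (SD, n = 4 each), with resmetirom replicate 1 at 7.54% and the others at 17.8% to 25.1%. An exact permutation test, 2-sided, gave p = 0.0286, the smallest that 4 against 4 libraries allow, or 0.0667 adjusted over 7 library measures.

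**Figure D2:**
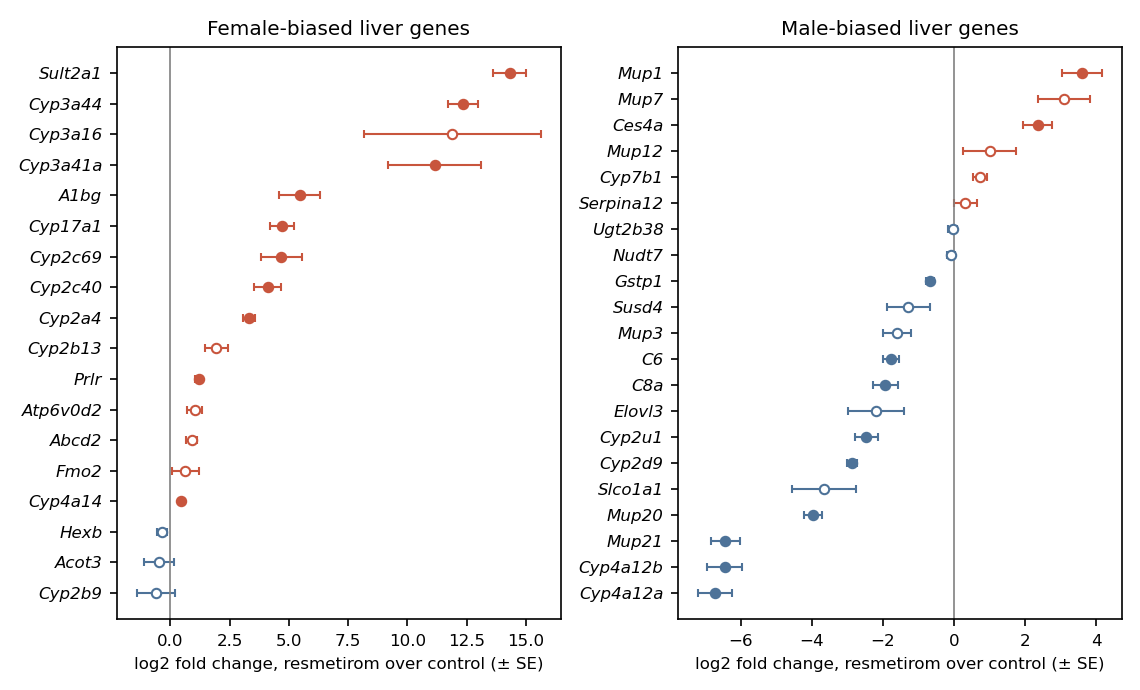
Fitted log2 fold changes, resmetirom over control, of the tested members of the lists of female-biased (left) and male-biased (right) liver genes, 4 libraries per group. Points are edgeR estimates and bars are 1 SE, filled where the adjusted p is under 0.05, red above 0 and blue below; the estimates of Sult2a1, Cyp3a44, Cyp3a16 and Cyp3a41a, with 0 to 3 counts in the control group, depend on the prior count of the fit.

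**Figure D3:**
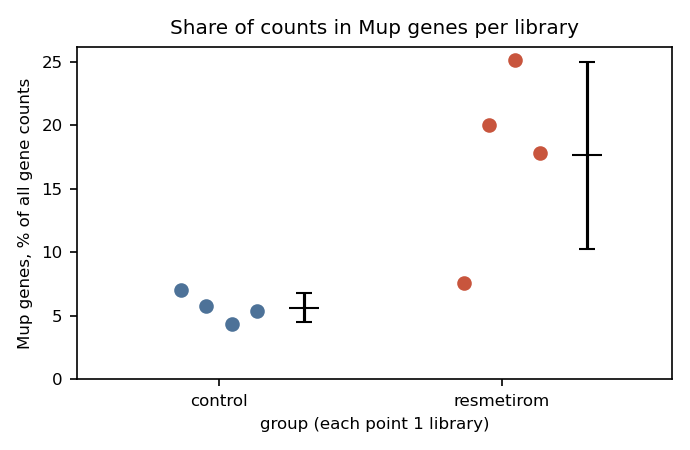
Share of all gene counts taken by the Mup genes in each library, in percent, by group. Each point is 1 library, and the black marks are the mean ± SD of the group (n = 4); the control libraries lie between 4.32% and 7.05%, and the resmetirom libraries at 7.54% and from 17.8% to 25.1%.

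Genes of xenobiotic and glutathione metabolism moved both ways. Of 19 tested targets of the nuclear receptors CAR and PXR, 3 rose and 4 fell (5 and 5 when adjusted over the list alone). Cyp3a11, the main drug-metabolizing P450 of mouse liver, fell by 1.65 on the log2 scale (SE 0.18, adjusted p = 0.000401) and the carboxylesterase gene Ces2a was at -1.16 (SE 0.10, adjusted p = 6.19e-05), while Ugt1a1 was at 0.74 (SE 0.11, adjusted p = 0.00173). The median of this list was -0.25, its mean 0.53, through Sult2a1, and its camera direction down (adjusted p = 0.544). This median was -0.55 with library sizes only, -0.73 on the log2(TPM + 1) and log2(TPM + 0.1) scales, -0.16 without control replicate 2 and -0.15 without control replicate 3. CAR and PXR targets had 5 higher and 4 lower with DESeq2, and 2 and 11 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Among 21 NRF2 target and glutathione genes, 1 rose and 5 fell (1 and 5 when adjusted over the list alone), with the glutathione transferase genes Gsta1 at -3.44 (SE 0.44, adjusted p = 0.00153), Gsta2 at -1.47 (SE 0.16), Gstm1 at -0.87 (SE 0.11) and Gstm2 at 0.66 (SE 0.10). The camera adjusted p of this list was 0.0553. It passed with voom weights (adjusted p = 0.0422), without control replicate 2 (adjusted p = 0.0160), without resmetirom replicate 1 (adjusted p = 0.0356) and without resmetirom replicate 3 (adjusted p = 0.0272). With a replicate block it also passed (adjusted p = 0.0427), but not with an estimated correlation (adjusted p = 0.668) or with fry (adjusted p = 0.106). NRF2 targets had 0 higher and 8 lower with library sizes only, and 0 and 12 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Bile acid genes were higher in 4 and lower in 2 of 22 (8 and 4 when adjusted over the list alone). The bile salt uptake transporter gene Slc10a1 rose by 0.92 (SE 0.16, adjusted p = 0.00629) and the basolateral exporter gene Abcc3 had -2.80 (SE 0.22, adjusted p = 0.000128). The list had a median of 0.19, a mean of -0.0054 and a camera direction of up (adjusted p = 0.0917). The bile acid list passed with library sizes only (adjusted p = 0.0396) and without control replicate 2 (adjusted p = 0.0325). The first of these calls is relative to other genes, as the median of all tested genes was -0.31 with library sizes only. The bile acid median was -0.12 with library sizes only and -0.32 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Bile acid genes had 2 higher and 5 lower with library sizes only, 7 and 3 with DESeq2, 2 and 2 without a low-count filter, and 2 and 8 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 3 higher and 1 lower without control replicate 2 or 3 or resmetirom replicate 2, 1 and 1 without control replicate 4 or resmetirom replicate 4, and 2 and 3 without resmetirom replicate 1. Pericentral genes were higher in 3 and lower in 2 of 18 (4 and 2 when adjusted over the list alone), including Cyp1a2 at -1.94 (SE 0.19, adjusted p = 0.000246), and periportal genes were higher in 4 and lower in 3 of 17 (6 and 3 when adjusted over the list alone), including Tat at 1.63 (SE 0.27, adjusted p = 0.0110) and Cdh1 at 1.05 (SE 0.18). Neither list was called (adjusted p = 0.842 and 0.746), and the periportal median of -0.12 and mean of 0.042 differed in sign, with a camera direction of up. Pericentral genes had 1 higher and 4 lower with library sizes only, and 0 and 7 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Periportal genes had 2 higher and 4 lower with library sizes only, and 1 and 8 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 3 higher and 1 lower without control replicate 3 or 4, and 4 and 1 without resmetirom replicate 3. The periportal median was -0.42 with library sizes only, -0.45 on the log2(TPM + 1) and log2(TPM + 0.1) scales, -0.042 without control replicate 2, -0.069 without control replicate 3 or resmetirom replicate 1, -0.059 without control replicate 4, 0.010 without resmetirom replicate 3 and 0.005 without resmetirom replicate 4. Hepatocyte identity genes were higher in 3 and lower in none of 18 (6 and 2 when adjusted over the list alone), including the fetuin gene Ahsg at 0.61 (SE 0.10, adjusted p = 0.00444), with a camera adjusted p of 0.166. Hepatocyte identity genes had 3 higher and 1 lower with upper-quartile factors or without a low-count filter, 0 and 6 with library sizes only, 6 and 2 with DESeq2, and 0 and 8 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 2 higher and 1 lower without control replicate 3, and 3 and 1 without resmetirom replicate 3. With library sizes only, the calls of Ugt1a1 (adjusted p = 0.0528), Gstm2 (adjusted p = 0.0943) and Ahsg (adjusted p = 0.1) were lost. None of 22 genes of glucose and glycogen metabolism was called, over all genes or adjusted over the list alone, the smallest p being that of Pfkl at -0.29 (SE 0.10, adjusted p = 0.116), which passed with library sizes only (adjusted p = 0.00688). Of these, 3 members had an unadjusted p under 0.05 in edgeR, 0 were called by DESeq2, and the list was not called (adjusted p = 0.791). Glucose and glycogen genes had 0 higher and 4 lower with library sizes only, and 0 and 6 on the log2(TPM + 1) and log2(TPM + 0.1) scales.

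Genes of fibrosis and inflammation showed few calls. Of 31 collagen and fibrogenic genes, 1 rose and 2 fell (1 and 3 when adjusted over the list alone), with a median of -0.25. The collagen median was -0.53 with library sizes only, -0.46 on the log2(TPM + 1) scale, -0.65 on the log2(TPM + 0.1) scale, -0.091 without control replicate 3, -0.54 without resmetirom replicate 1 and -0.090 without resmetirom replicate 2. Col3a1 was at -1.06 (SE 0.25, adjusted p = 0.0474) and lost its call without control replicate 1, 3 or 4 or resmetirom replicate 2, 3 or 4 (adjusted p = 0.0641 to 0.144), with upper-quartile factors (adjusted p = 0.0583) and without a low-count filter (adjusted p = 0.0661). The member called higher, Fn1 at 0.41 (SE 0.11, adjusted p = 0.0491), kept its call without control replicate 2 but lost it without each other library (adjusted p = 0.0524 to 0.162) and with library sizes only (adjusted p = 0.575), with limma-voom (adjusted p = 0.0501) and without robust estimation (adjusted p = 0.0615). Col1a1 at -1.02 (SE 0.42, adjusted p = 0.243) passed without resmetirom replicate 1 (adjusted p = 0.0258), and Acta2 was at -0.20 (SE 0.29, adjusted p = 0.8). Timp1 had 53 counts in all libraries together and was not tested. The list's call by camera (adjusted p = 0.0451) was lost without control replicate 3 or 4 or resmetirom replicate 2 or 4 (adjusted p = 0.0664 to 0.296). It was also lost with library sizes only, with voom weights and with the filter of at least 1 CPM in 4 samples (adjusted p = 0.0514 to 0.823). It was adjusted p = 0.821 with an estimated correlation, and 17 of 35 splits of the libraries, the real one included, gave as small a p. Collagen and fibrogenic genes had 1 higher and 1 lower with upper-quartile factors or without a low-count filter, 0 and 6 with library sizes only, 0 and 2 with limma-voom or without robust estimation, and 0 and 10 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 0 higher and 1 lower without control replicate 1, 3 or 4 or resmetirom replicate 2, 3 or 4, 1 and 1 without control replicate 2, and 0 and 3 without resmetirom replicate 1. The lists of endothelial cells and of lipid-associated macrophages were called lower as well, with medians of -0.36 and -0.35 (adjusted p = 0.000849 and 0.00392, and adjusted p = 0.668 for each with an estimated correlation). Stellate cell markers had no calls by edgeR or DESeq2 among 14 genes, and 0 at an unadjusted p under 0.05 (list adjusted p = 0.633). Stellate cell markers had 0 higher and 1 lower with library sizes only, and 0 and 3 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Of 25 acute phase genes none rose and 3 fell (0 and 4 when adjusted over the list alone), Saa3 at -1.41 (SE 0.19, adjusted p = 0.00102), Orm1 at -1.19 (SE 0.17, adjusted p = 0.00296) and Orm2 at -1.95 (SE 0.27, adjusted p = 0.00161). The list had an adjusted p of 0.0553. Camera called it lower with voom weights (adjusted p = 0.0369), without control replicate 3 (adjusted p = 0.00857), without control replicate 4 (adjusted p = 0.0127) and without resmetirom replicate 3 (adjusted p = 1.47e-05). Acute phase genes had 0 higher and 8 lower with library sizes only, 0 and 6 with DESeq2, and 0 and 13 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 1 higher and 3 lower without control replicate 2, and 0 and 7 without resmetirom replicate 3. In contrast to this list, the GO term acute-phase response was enriched among higher genes, with 5 against 0.701 expected (adjusted p = 0.0408), Ahsg, Ugt1a1 and Fn1 among them. With library sizes only, the calls of Ahsg, Ugt1a1 and Fn1 were lost. Among 24 stress response genes 1 rose and 2 fell (3 and 2 when adjusted over the list alone), with a median of 0.02 and a mean of -0.035. They were the asparagine synthetase gene Asns at 0.91 (SE 0.18, adjusted p = 0.0135), lost without control replicate 4 (adjusted p = 0.0559), Chac1 at -2.04 (SE 0.44, adjusted p = 0.0200), lost without control replicate 1, 3 or 4 or resmetirom replicate 1, 2 or 4 (adjusted p = 0.0520 to 0.0720) and with limma-voom (adjusted p = 0.122), and Trib3. Trib3 was at -1.24 (SE 0.31, adjusted p = 0.0490), a call lost without any one library except resmetirom replicate 1 (adjusted p = 0.0699 to 0.125), with upper-quartile factors (adjusted p = 0.0691) and without robust estimation (adjusted p = 0.0505). The list was not called (adjusted p = 0.544). It was called higher without control replicate 1 (adjusted p = 0.0128). Stress response genes had 1 higher and 1 lower with upper-quartile factors, with limma-voom or without robust estimation, 1 and 4 with library sizes only, 2 and 2 with DESeq2, 0 and 8 on the log2(TPM + 1) scale, and 0 and 7 on the log2(TPM + 0.1) scale. They had 3 higher and 0 lower without control replicate 1, 1 and 1 without control replicate 2 or resmetirom replicate 1 or 3, 1 and 0 without control replicate 3 or resmetirom replicate 2 or 4, and 0 and 0 without control replicate 4. The stress response median was -0.29 with library sizes only, and it was between -0.052 and 0.34 without any one library, where each of the 8 moved it.

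Of the lists of cell type markers, those of T and NK cells, endothelium and lipid-associated macrophages were called, with 1 member called among them (adjusted p = 8.14e-05, 0.000849 and 0.00392). All 3 calls were lost, with adjusted p = 0.273, 0.668 and 0.668 with an estimated correlation, and 4, 8 and 4 of the 35 splits gave as small a p. With fry the adjusted p was 0.0303, 0.193 and 0.106 in the same order. T cell and NK cell markers had a median of 1.24 over 10 tested genes. This median was 0.35 on the log2(TPM + 1) scale, 0.66 on the log2(TPM + 0.1) scale and 0.80 without resmetirom replicate 2. None of the 10 was called over all genes or adjusted over the list alone. Of these 10, 6 had an unadjusted p under 0.05 and 1 was called by DESeq2, which tested 21 members. T and NK cell markers had 1 higher and 0 lower of the 21 tested with DESeq2. They had 1 higher and 0 lower without resmetirom replicate 3. Nkg7 was at 0.305 ± 0.197 CPM in the control libraries and 1.38 ± 0.831 CPM in the resmetirom libraries (SD, n = 4 each), a log2 fold change of 2.16 (SE 0.65, adjusted p = 0.0897). Nkg7 passed without resmetirom replicate 3 (adjusted p = 0.0165) and with DESeq2 (adjusted p = 0.0298). Endothelial markers had a median of -0.36 with none of 15 called (0 and 5 when adjusted over the list alone, 6 at an unadjusted p under 0.05, 1 called by DESeq2). The endothelial median was -0.65 with library sizes only, -0.75 on the log2(TPM + 1) scale and -0.83 on the log2(TPM + 0.1) scale. Endothelial markers had 0 higher and 5 lower with library sizes only, 0 and 1 with DESeq2, and 0 and 13 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 0 higher and 3 lower without resmetirom replicate 1. The smallest p was that of Tek at -0.40 (SE 0.11, adjusted p = 0.0693), which passed with library sizes only (adjusted p = 0.00618) and with DESeq2 (adjusted p = 0.0385). Lipid-associated macrophage markers had a median of -0.35 with none of 16 higher and 1 lower (1 and 5 when adjusted over the list alone), the lipoprotein lipase gene Lpl at -1.81 (SE 0.26, adjusted p = 0.00474), which other cells can also express. Trem2 was at -0.46 (SE 0.24, adjusted p = 0.357). The macrophage median was -0.66 with library sizes only, -0.81 on the log2(TPM + 1) scale and -0.85 on the log2(TPM + 0.1) scale. This list had 0 higher and 8 lower with library sizes only, 1 and 5 with DESeq2, 0 and 2 with limma-voom or with the filter of at least 1 CPM in 4 samples, 0 and 3 without robust estimation, and 0 and 13 on the log2(TPM + 1) and log2(TPM + 0.1) scales. It had 0 higher and 3 lower without control replicate 1 or resmetirom replicate 1. Library-size scaling ended the call of the macrophage list (adjusted p = 0.195).

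The list of Kupffer cells was not called (0 of 16 genes, list adjusted p = 0.544), with Adgre1 at -0.04 (SE 0.31, adjusted p = 0.969), and its median of -0.11 and mean of 0.0095 differed in sign. The Kupffer median was -0.39 with library sizes only, -0.65 on the log2(TPM + 1) scale, -0.66 on the log2(TPM + 0.1) scale, -0.18 without control replicate 2 or 4, -0.011 without control replicate 3, -0.35 without resmetirom replicate 1, -0.19 without resmetirom replicate 2, -0.014 without resmetirom replicate 3 and 0.048 without resmetirom replicate 4. Kupffer cell markers had 0 higher and 6 lower on the log2(TPM + 1) and log2(TPM + 0.1) scales. No call was made either for monocytes (1 higher of 12, list adjusted p = 0.474), B and plasma cells (1 higher of 11, list adjusted p = 0.256) and dendritic cells (0 of 12, list adjusted p = 0.276). Cytokines and chemokines (0 of 17, list adjusted p = 0.237), interferon-stimulated genes (0 of 29, list adjusted p = 0.367), cell cycle genes (0 of 19, list adjusted p = 0.746), circadian clock genes (0 of 21, list adjusted p = 0.215) and immediate early genes (0 of 16, list adjusted p = 0.796) were not called either. Ccl2 was at -1.27 (SE 0.75, adjusted p = 0.439). Adgre1 was 0.070 to 0.14 without control replicate 3 or resmetirom replicate 3 or 4. Adjusted over the list alone, clock genes had 1 higher and 3 lower, and 0 of the Kupffer cell, dendritic cell, cytokine, interferon-stimulated, cell cycle and immediate early genes were called. At an unadjusted p under 0.05 there were 0 Kupffer cell, 4 dendritic cell, 5 cytokine, 2 interferon-stimulated, 0 cell cycle, 5 clock and 2 immediate early genes. DESeq2 called 0, 0, 2, 0, 0, 4 and 0 genes of these lists. Dendritic cell genes had 0 higher and 2 lower with library sizes only, and 0 and 5 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 0 higher and 1 lower without resmetirom replicate 1. Cytokines and chemokines had 0 higher and 1 lower with library sizes only, 1 and 1 of the 27 tested with DESeq2, 1 and 0 without robust estimation, and 0 and 7 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 1 higher and 0 lower without resmetirom replicate 4. Interferon-stimulated genes had 0 higher and 1 lower with library sizes only, and 0 and 11 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Cell cycle genes had 0 higher and 3 lower on the log2(TPM + 1) and log2(TPM + 0.1) scales. Clock genes had 0 higher and 5 lower with library sizes only, 1 and 3 with DESeq2, 1 and 1 with limma-voom, 0 and 1 without a low-count filter, and 0 and 9 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 0 higher and 1 lower without control replicate 1 or resmetirom replicate 2, 1 and 0 without control replicate 2, and 0 and 2 without resmetirom replicate 1. Immediate early genes had 0 higher and 1 lower with library sizes only, 0 and 3 on the log2(TPM + 1) scale, and 0 and 2 on the log2(TPM + 0.1) scale. The member called higher was the immunoglobulin J chain gene Jchain for B and plasma cells, at 1.44 (SE 0.30, adjusted p = 0.0157). For monocytes it was the fibronectin gene Fn1, a call lost without any one library except control replicate 2 (adjusted p = 0.0524 to 0.162). Each was also called when adjusted over the list alone. Monocyte markers had 0 higher and 0 lower with library sizes only, with limma-voom or without robust estimation, and 0 and 3 on the log2(TPM + 1) and log2(TPM + 0.1) scales. They had 0 higher and 0 lower without control replicate 1, 3 or 4 or any one resmetirom replicate. B and plasma cell markers had 1 higher and 1 lower with library sizes only, and 1 and 2 on the log2(TPM + 1) and log2(TPM + 0.1) scales. Camera called the B and plasma cell list higher with library sizes only (adjusted p = 0.00202), relative to other genes, where the median of all tested genes was -0.31. Among 9 cholangiocyte markers the keratin gene Krt23 fell by 4.93 (SE 0.37, adjusted p = 2.96e-05), the 1 call also when adjusted over the list alone. The list had a median of 0.26, a mean of -0.41 and an adjusted p of 0.920. The cholangiocyte median was -0.044 with library sizes only, 0.43 with DESeq2, -0.25 on the log2(TPM + 1) scale, -0.28 on the log2(TPM + 0.1) scale and 0.16 without control replicate 3. Cholangiocyte markers had 0 higher and 2 lower with library sizes only or on the log2(TPM + 0.1) scale. Erythrocyte markers had 1 lower of 6, Alas2 at -2.52 (SE 0.29, adjusted p = 0.00158), as when adjusted over the list alone, with a list adjusted p of 0.397. The erythrocyte list had a median of 0.76, a mean of 0.18 and a camera direction of up, with the hemoglobin genes, not called, at 0.74 (Hbb-bs), 0.78 (Hba-a1), 0.90 (Hba-a2) and 0.93 (Hbb-bt). The erythrocyte median was 0.47 with library sizes only, 0.37 on the log2(TPM + 1) scale, 0.38 on the log2(TPM + 0.1) scale, 0.48 without control replicate 1 and 0.45 without resmetirom replicate 1. Too few members were tested for a list test of neutrophils (0 called of 4), pancreatic acinar cells (Cela2a higher of 2, and both when adjusted over the list alone, Cela2a at 0.902 CPM with resmetirom), adipocytes (Fabp4 lower of 4, and 3 lower when adjusted over the list alone), skeletal muscle (0 tested) and sex-linked transcripts (0 called of 4 Y-linked genes). Neutrophil markers had 0 higher and 1 lower on the log2(TPM + 1) and log2(TPM + 0.1) scales. Pancreatic acinar markers had 0 higher and 0 lower with the filter of at least 1 CPM in 4 samples. Adipocyte markers had 0 higher and 3 lower with library sizes only or on the log2(TPM + 1) and log2(TPM + 0.1) scales, 0 and 4 of the 7 tested with DESeq2, 0 and 2 with limma-voom, and 0 and 2 of the 7 tested without a low-count filter. Y-linked genes had 0 higher and 2 lower on the log2(TPM + 1) and log2(TPM + 0.1) scales.

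Further large changes lay outside the lists. Gldn, which encodes gliomedin, had no counts in the control group and was at least 91.2-fold higher, and the aldo-keto reductase gene Akr1c18 rose by 8.90 (SE 0.35, adjusted p = 5.66e-08). Akr1c18 had 5 counts over the control and 1969 over the resmetirom libraries, so the size of its fitted change depends on the prior count. Nox4, a hydrogen peroxide-producing NADPH oxidase (ENSMUSG00000030562, chromosome 7, 87246096 to 87398710), was at 41.1 ± 7.39 CPM in the control libraries and 3.76 ± 2.25 CPM in the resmetirom libraries (SD, n = 4 each), a change of -3.46 (SE 0.40, adjusted p = 0.00207). Gsta13 had -4.24 (SE 0.51, adjusted p = 0.00116) and Nat8f5 -4.20 (SE 0.67, adjusted p = 0.00347). In the pathway annotation carried by the deposited table, 25 of 330 KEGG pathways were enriched among higher and 23 among lower genes (1-sided hypergeometric test against annotated tested genes, adjusted p under 0.05). Steroid biosynthesis held 11 higher genes against 0.603 expected (adjusted p = 1.44e-10) and oxidative phosphorylation 26 against 4.22 (adjusted p = 9.01e-12). The hypergeometric test treats genes as independent. For the nuclear-encoded and mitochondrially encoded lists, camera with an estimated correlation gave adjusted p = 0.567 and 0.287. Most calls of both lists were lost with library sizes only. Steroid hormone biosynthesis was enriched in both directions, with 14 lower genes against 1.73 expected (adjusted p = 3.28e-07) and 14 higher against 2.38 (adjusted p = 1.50e-06). Among lower genes, glutathione metabolism held 10 against 1.48 expected (adjusted p = 8.39e-05), complement and coagulation cascades 11 against 2.02 (adjusted p = 0.000156) and ABC transporters 7 against 0.984 (adjusted p = 0.00111).

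The authors' deposited table holds its own comparison of the same libraries, whose fold change matched the log2 ratio of the group means of TPM in 99.98% of its rows within 0.01. At its adjusted p under 0.05, the authors' deposited table lists 190 genes higher and 5192 lower with resmetirom, so that 96.5% of its calls are lower. Over the genes tested here, the median log2 fold change in the authors' deposited table was -0.49. Of the 560 genes called by edgeR, 385 were called in the authors' deposited table too, and 502 had the same sign there. Of the 5143 genes that it calls lower and that were tested here, 935 had an edgeR log2 fold change above 0. With limma-trend on log2(TPM + 1), edgeR calls of Me1 (adjusted p = 0.350), Cpt1a (adjusted p = 0.687), Slc16a10 (adjusted p = 0.402), Fads2 (adjusted p = 0.0881), Slc10a1 (adjusted p = 0.103), Apoa4 (adjusted p = 0.223), Apoc3 (adjusted p = 0.561), Cox7b (adjusted p = 0.828), mt-Nd6 (adjusted p = 0.223), mt-Cytb (adjusted p = 0.732), mt-Co3 (adjusted p = 0.958), mt-Co2 (adjusted p = 0.968), Asns (adjusted p = 0.146), Cdh1 (adjusted p = 0.0661), Ugt1a1 (adjusted p = 0.3), Gstm2 (adjusted p = 0.436) and Ahsg (adjusted p = 0.622) were not reached. On that scale Dio1 (adjusted p = 0.0307), Thrb (adjusted p = 0.0115), Col1a1 (adjusted p = 0.0196), Trem2 (adjusted p = 0.0170), Pfkl (adjusted p = 0.0104) and Tek (adjusted p = 0.00801), not called by edgeR, passed. The call of Asns was also lost without control replicate 4 (adjusted p = 0.0559).

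**Figure D4:**
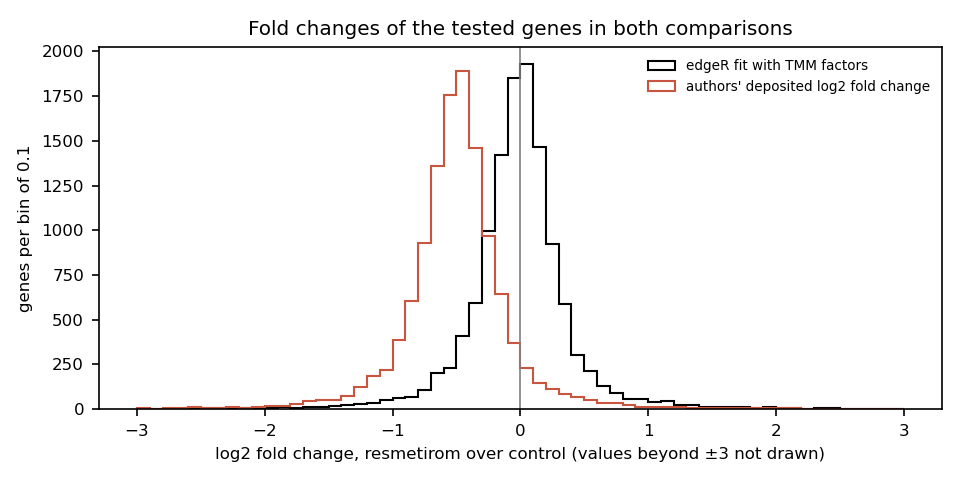
Distribution of the log2 fold change, resmetirom over control, of the 12207 tested genes, as number of genes per bin of 0.1, in the edgeR fit with TMM factors (black) and in the authors' deposited table (red). The median is -0.0043 in the edgeR fit and -0.49 in the authors' deposited table.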

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

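No test in this part was chosen after its result was seen. In 240 groups of 4 libraries, made of the log2 CPM of each named gene and 6 library measures in each group, 16 had 1 library whose gap to its nearest neighbour took up more of the group's range than 95% of such groups would show by chance, where about 12 were expected. That is close to the number that chance gives, and no explanation was tested. The gap took up 1 of the range for Sult2a1 in control replicate 3, which held all 3 control counts, and equally 1 for Cyp3a41a in control replicate 3, with the other control libraries at 0 counts. Among the resmetirom libraries, Sult2a2 was low in replicate 2 (7.61 against 8.84 to 8.92 log2 CPM, a gap of 0.937 of the range), and so was Dio1 (6.16 against 6.95 to 7.07, 0.866). Replicate 1 was low for Cyp4a12b (-2.60 against 0.25 to 0.83, 0.833) and Mup21 (-2.60 against -0.35 to -0.04, 0.879) and high for Cyp2c29 (8.57 against 7.77 to 7.81, 0.946). Replicate 3 was low for Cps1 (12.11 against 12.54 to 12.57, 0.936), and replicate 4 was low for Cyp4a31 (7.69 against 7.84 to 7.87, 0.837) and Prlr (6.32 against 6.66 to 6.68, 0.960). Among the control libraries, replicate 3 was high for Krt23 (4.88 against 3.85 to 3.99, 0.865) and the scavenger receptor gene Marco (5.23 against 3.82 to 3.97, 0.892). Replicate 1 was high for Scd1 (13.68 against 13.16 to 13.24, 0.846) and low for Trem2 (1.58 against 2.09 to 2.19, 0.843). Replicate 4 was low for Jchain (-0.08 against 0.98 to 1.13, 0.875), and replicate 2 was low for Chac1 (0.40 against 2.1 to 2.36, 0.867).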

How the results depend on the processing

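The alternatives on TPM and without the Mup genes were chosen after the data were seen. The counts of 317 higher and 243 lower genes stayed within 1.5 times under RLE and upper-quartile factors, without the 20 most abundant genes, with limma-voom, without robust estimation, under both filters, with assigned symbols only and without the Mup genes. With library sizes only they were 151 and 1961. They were 190 and 5192 in the authors' deposited comparison, and 524 and 385 with DESeq2, which held all 560 called genes. At least 2-fold changes numbered 127 and 111, and an adjusted p under 0.01 left 152 and 113, as stricter thresholds must. On log2(TPM + 1) they were 127 and 4635, on log2(TPM + 0.1) 128 and 4593, and on log2(TPM + 1) with no filter 117 and 3688, and the cause of the TPM counts was tested only as far as the Mup share goes. Leaving out 1 library in turn gave 182 to 313 higher and 149 to 238 lower genes, with the lowest of each without control replicate 4, where fewer samples were fitted. The 7 lists higher and 4 lower became 1 and 0 with an estimated correlation. With fry 2 lists were lower (male-biased and sterol efflux genes). Fry called higher the cholesterol synthesis, thyroid hormone responsive, female-biased, mitochondrially encoded, nuclear-encoded oxidative phosphorylation and T and NK cell lists. Of the lists that camera called, it did not call fatty acid oxidation, collagen, endothelial and lipid-associated macrophage genes. With library sizes only 2 lists were lower, and without single libraries 7 to 10 lists were higher and 3 to 7 lower (7 without resmetirom replicate 3). The cause was not tested. The replicate numbers, which the groups share, did not pair the libraries: deviations of same-numbered libraries correlated at r = -0.325, 0.184, -0.186 and -0.0612, and 1 of the 4 control libraries correlated best with its own number. With a replicate block the fit called 240 genes higher and 166 lower, with 0 of 20 Mup genes higher, and 7 lists higher and 5 lower. Alternatives to the reported values of named genes kept the direction and the side of the threshold in 2136 of 2384 cases, lost a call in 163, gained one in 58 and reversed in 27. The camera direction of no called list reversed, though with library sizes only the medians of nuclear-encoded oxidative phosphorylation and of fatty acid oxidation fell below 0, and 23 of 175 alternatives ended a list's call. The reversed log2 fold changes were, on log2(TPM + 1), Klf9 -0.013, Abcb4 -0.11, Bdh1 -0.040, Cyp4a14 -0.036, Uqcrb -0.11, Cox7a2 -0.061, Cox6b1 -0.11, Fn1 -0.093, Hand2 -0.088, Iigp1 -0.25, Apoh -0.11. On log2(TPM + 0.1) they were Klf9 -0.013, Abcb4 -0.11, Bdh1 -0.040, Cyp4a14 -0.036, Uqcrb -0.11, Cox7a2 -0.061, Cox6b1 -0.11, Fn1 -0.094, Hand2 -0.11, Iigp1 -0.25, Apoh -0.11, and with library sizes only Iigp1 -0.035. Without single libraries, Thrsp was -0.56 to 0.14 and Adgre1 -0.42 to 0.14. The cause of these was not tested. Alternatives on FPKM, fixed before the data were examined, were not run, since the table holds TPM. At this depth and with 4 libraries a group, 34% of 1.5-fold changes were recovered in simulation, for genes with a mean of at least 1 CPM. Genes not called may thus have changed by that much.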

Other observations

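The tests of library scaling, of hepatocyte share, of LXR targets, of Y-linked transcripts and of single-copy genes, and of a general fall in transcripts, were chosen after the result was seen; those of the Mup share, of a single library, of the growth hormone axis and of other splits of the libraries were fixed before.

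Members of the Mup family, which encode the major urinary proteins secreted by the liver, moved apart. Of 20 tested members, 7 rose and 2 fell. The family had 10 higher and 4 lower with library sizes only, 3 and 1 of the 14 tested without the 20 most abundant genes, 11 and 4 with DESeq2, and 10 and 5 on the log2(TPM + 1) and log2(TPM + 0.1) scales. It had 3 higher and 2 lower without control replicate 2, 1 and 2 without control replicate 4, 13 and 3 without resmetirom replicate 1, and 6 and 4 without resmetirom replicate 3. With a replicate block, whose numbers did not pair the libraries, it had 0 higher and 2 lower. Mup15 was not called without control replicate 4 (adjusted p = 0.0561), nor were Mup15 and Mup19 with that block (adjusted p = 0.135 for each). Mup19 went from 8479 to 67864 CPM and Mup15 from 1034 to 34802 CPM, while Mup20, the most abundant member in the control libraries, went from 15540 to 999 CPM. Genes of growth hormone signalling, which sets the sex bias of many liver genes, were at -0.21 (SE 0.14) for the receptor gene Ghr, 0.02 (SE 0.13) for Stat5b, 0.14 (SE 0.77) for Socs2, -0.60 (SE 0.61) for Cish and -0.12 (SE 0.17) for Igf1, none of them called by edgeR.

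The gene counts were compared with those of the other splits of the 8 libraries into 2 groups of 4, 35 splits in all. Only 1 of the 35 splits, the real one, gave as many as 317 higher or 243 lower genes, and the highest count of another split was 1. A first rank among 35 splits is the most this test can give, and the other splits mix the groups, which widens their spread. The test therefore cannot exclude chance by itself. For the gene lists, 16 of the 35 splits gave at least 7 lists in 1 direction, where the highest other count was 12, and 29 gave at least 4. Camera with the preset correlation called a median of 10 lists in the other 34 splits. For single lists, the real split gave the smallest p of the 35 for cholesterol synthesis, female-biased, male-biased and thyroid hormone responsive genes. For the others, 2 splits gave as small a p for both oxidative phosphorylation lists, 4 for fatty acid oxidation, lipid-associated macrophages and T and NK cells, 8 for endothelium and 17 for collagen genes. Splits that put 3 control libraries on 1 side still hold part of the group difference, and 1 of these gave the count of 12 lists. In another split than the real one, cholesterol synthesis reached a camera p of 4.25e-20. These counts of splits are therefore not rates of calls by chance.

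The authors' deposited table calls far more genes lower than higher. A candidate explanation is the larger share of Mup transcripts in the resmetirom libraries, which lowers the values of all other genes when each library is scaled to its own total. With library sizes only, the median log2 fold change of the tested genes was -0.31, and leaving out the Mup genes brought it to -0.12, which removed 62.5% of the shift, and the calls became 226 higher and 438 lower. In the authors' deposited TPM, Mup genes made up 10.5% ± 2.05 of the control and 28.4% ± 10.9 of the resmetirom total (SD, n = 4 each), and rescaling without them took the median log2 ratio from -0.49 to -0.17. Whether most transcripts fell per cell cannot be told, since relative counts hold no external standard. The cause of the remaining shift of -0.12 was not tested.

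Cholesterol synthesis genes rose together. Whether diet or vehicle differed between the groups is not given, so neither can be told apart from the drug here. Library scaling as the cause is argued against by the list's median of 2.18 with library sizes only, and a single deviating library by the fact that in 100% of the 25 members all 4 resmetirom libraries lay above all 4 control libraries. A larger share of hepatocytes would lift other hepatocyte genes as well, but the median of the hepatocyte identity list was 0.14 (SE 0.11 of its mean; 0.071 without resmetirom replicate 3), against 2.43. Less sterol in the cells may lie behind the rise: 11 tested targets of LXR, a receptor activated by oxysterols, had a median of -0.69, with 6 of them called lower and 0 higher (camera, 1-sided p = 2.34e-09; 2-sided p = 0.0137 with an estimated correlation). All 6 belonged to lists whose values had been seen, Abcg5 and Abcg8 among them, and sterol levels were not measured, so this remains a hypothesis.

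Of the male-biased genes 9 fell and 2 rose, while 10 female-biased genes rose and 0 fell, but female animals among the resmetirom libraries would lack Y-linked transcripts, of which the lowest resmetirom library held 86.2% of the control mean of 4 Y-linked genes. Reads shared between near-identical copies cannot be the whole cause, since 14 single-copy members, with male-biased genes turned in sign, had a median of 1.24, with 6 called in the direction of the lists and 0 against it (camera p = 2.71e-07; p = 0.00982 with an estimated correlation). An altered growth hormone axis may account for such a switch, but Bcl6, a male-biased repressor, was at 0.89 (SE 0.98, edgeR adjusted p = 0.726), and the explanation stays open. The female-biased repressor gene Cux2, which the low-count filter left out, had 1 to 6 counts per control and 2 to 69 per resmetirom library, 69 of them in resmetirom replicate 1. Its log2 fold change was 3.46 in edgeR without the filter (adjusted p = 0.0835), not called, and 3.52 with DESeq2 (adjusted p = 0.00521), called. A difference in diet or vehicle between the groups could not be tested for the sex-biased genes either.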
